A study of Mus musculus with 16 samples.

How the data were processed

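RNA of the left and the right ventricle of 8 mouse embryos was measured in 16 sequencing libraries. Per the labels, 3 embryos had HLHS and 5 were littermate controls, from litters of 3 stages, and libraries were made with a TruSeq kit. The deposited table holds whole-number counts of reads per gene that the authors made; per the submitters' processing notes, the tools named are TopHat2 2.0.9, Picard, HTSeq 0.5.4p5 and edgeR 3.4.2, with the mouse build mm9. Whether the counting used strand, whether duplicate reads were removed and which annotation was used are not given in the sources used here, so reads of overlapping, antisense or near-identical genes, such as those of the globin and protocadherin families, cannot be told apart. No coordinates are given, because the reference at hand is of another build. The authors' own comparisons were not used here. Pcdha9 was not analysed here, because no entry of the count table matches its symbol.

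Samples were grouped by the phenotype, side, stage and embryo in the labels. The table holds 37991 genes; symbols were found for 32919 of them (86.6%), and those without a symbol hold 0.492% of the counts. Total counts per library ran from 17081273 to 28648645, and intervals on shares cover counting error only, since reads without molecular identifiers are not independent molecules. No pair of libraries within a group agreed within sampling noise: over 26 pairs the lowest chi-square per degree of freedom was 7.51. Replicate numbers mark the embryo, so they pair the ventricles of 1 animal. In controls the deviations of left and right libraries of 1 embryo from their group means correlated with an r across genes of 0.494 to 0.80, against at most 0.633 for different embryos. These ranges overlap, and the group means mix stages, which both ventricles of an embryo share. The pairing thus rests on the labels, and these r do not test it.

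The counts were tested in R 4.3.3 with edgeR 4.0.16 (TMM factors, filterByExpr with a minimum count of 10 and a minimum total of 15, glmQLFit and glmQLFTest), with Benjamini-Hochberg adjustment and a threshold of 0.05. HLHS was compared with control in each ventricle with stage, which is also the litter, as a term. The difference between the ventricles in the HLHS effect was tested over all 16 libraries with the embryo as a block. Left was compared with right within embryos, in controls and in HLHS hearts. E17.5 was compared with E14.5 in controls on counts summed over both ventricles of an embryo. Log2 fold changes are given with standard errors. Levels in CPM, normalised read counts, are means over a group and, unlike the fold changes, are not matched by stage.

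Before the data were examined, 40 gene lists were fixed for heart muscle, metabolism, signalling, stress and other cell types, and cytosolic ribosomal protein genes were added by symbol, which made 41. In each comparison 40 were tested, since the thymus list had fewer than 3 members among the genes tested. Lists that passed with the preset correlation are reported, some by their median alone, and so are some that did not pass. Lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists of a comparison, with an estimated correlation (an adjusted p written as estimated) and with fry. Members are called higher or lower at an adjusted p under 0.05 over all genes, and again adjusted over the list alone.

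Genes are named by a rule fixed before the data were examined. It takes the 10 largest changes among genes past the threshold with an average log2 CPM of at least 2 and, for the HLHS and side comparisons, the same direction in every litter or embryo, leaving out unnamed gene models. It adds up to 4 members of each list that passed or had at least 3 members past the threshold, from which examples are given, and, whatever their values, Sap130, Pcdha9, Hand1, Hand2, Nppa, Nppb, Myh6, Myh7, Cdkn1a and Mki67. Where fewer than 10 genes passed, the 5 with the smallest p are given. Not every gene that the rule takes is named in the text. Xist and Ddx3y were read as a check that both ventricles of an embryo had the same sex.

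Each fit was tested on simulated data with 200 genes changed, drawn from those with higher counts, and the cell cycle list shifted by 0.4 on the log2 scale. Recovery of changed genes near the count filter was not measured. Of the genes changed 2-fold, 98.5% were called in the left ventricle, 95.5% in the right, 94.0% in the test of the difference between them, 100% in the control sides, 92.5% in the HLHS sides and 100% between stages, in steps of 15803, 15961, 16386, 16102, 15570 and 17488 genes. Of the calls, 10.1%, 5.86%, 4.19%, 8.03%, 12.2% and 7.36% were unchanged genes, where the threshold aims at 0.05 of all calls. The alternatives were DESeq2 size factors, DESeq2 1.42.0, limma-voom, no count filter, a filter of at least 1 CPM in 3 libraries, globin genes left out, fits without the block, all libraries in 1 fit, summed ventricles, single ventricles for the stage comparison, and each embryo left out in turn. A term for the sex of the embryo was chosen after seeing the data. Correlations of the HLHS effect with the stage change are across genes, which are not independent replicates. They were set beside 100 simulations, 4 splits of the controls and the 18 choices of 1 embryo per litter. The same choices were applied to the correlation between the ventricles and to the list scores after the results had been seen.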

Results

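Polyadenylated RNA was sequenced from the left and the right ventricle of 8 mouse embryos, which gave 16 libraries. Of these embryos, 3 had hypoplastic left heart syndrome (HLHS), a malformation with a small left ventricle, and 5 were littermates without it. The litters were taken on embryonic days (E): at E13.5, with 1 HLHS and 1 control embryo, and at E14.5 and E17.5, with 1 HLHS and 2 control embryos each, so stage and litter were the same variable. Each ventricle therefore had 3 HLHS and 5 control libraries. Total counts per library ran from 17081273 to 28648645. No gene held more than 1.37% of a library's counts (Myh7, the slow myosin heavy chain, in control right ventricle replicate 1; 95% Wilson interval 1.37 to 1.38%, counting error only). The comparisons ask how the small left ventricle and the right ventricle of HLHS hearts differ from those of littermates, and how the sides of the heart differ.

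The first principal component of the libraries held 43.1% of the variance and ordered them by stage. The second component held 12.9%. At every stage and on both sides the HLHS library had a lower first component score than its littermate controls, toward the earlier stages.

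**Figure D1:**
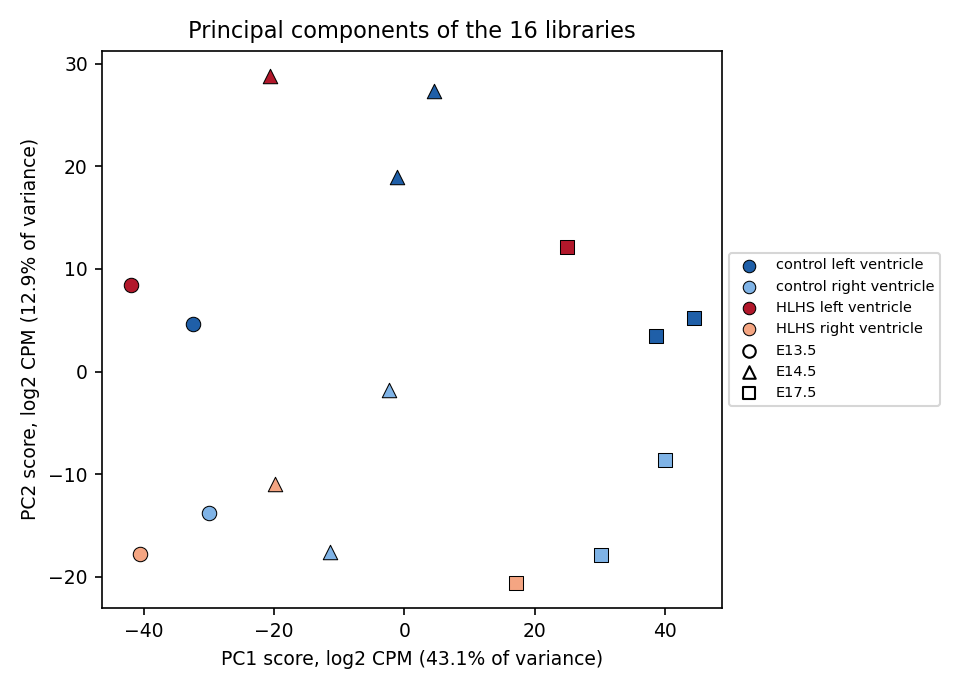
Scores of the 16 libraries on the first (43.1% of variance) and second (12.9%) principal components of log2 CPM; colour gives phenotype and side, symbol shape the stage. Each HLHS library lies to the left of the control libraries of its own stage and side.

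In the HLHS left ventricle, some genes of mitochondrial energy metabolism were lower, and some of hypoxia, TGF-beta and BMP signalling, cardiac stress and red blood cells were higher, than in littermate controls. As lists they passed in camera with a preset correlation and not with an estimated one (smallest adjusted p = 0.206). Ckmt2, the mitochondrial creatine kinase of striated muscle, fell by 2.18 ± 0.16 on the log2 scale (SE, 3 HLHS and 5 control libraries), a 4.53-fold change. Hmox1, the heme-degrading enzyme heme oxygenase 1, rose by 2.00 ± 0.11. Myh6, the fast myosin heavy chain of heart muscle, changed by −0.99 ± 0.22, while Myh7 had a log2 change of 0.03 ± 0.06. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment and stage as a term, 2043 of 15979 genes passed the threshold of 0.05, 986 higher and 1057 lower in HLHS. Of these, 134 were at least 2-fold higher and 184 at least 2-fold lower, and 2027 moved the same way in all 3 litters.

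The 10 largest changes in the left ventricle included those of Ckmt2 and Hmox1. Stmn4, a microtubule-destabilising stathmin (ENSMUSG00000022044), rose by 3.42 ± 0.40. Tagln, a smooth muscle actin-binding protein, rose by 1.98 ± 0.40. The peptide transporter gene Slc15a2 (−3.06 ± 0.78), the nucleoside transporter gene Slc28a2 (−2.21 ± 0.26), Dhrs7c (−2.04 ± 0.17), Clec3b (−1.94 ± 0.31) and Scara5 (−1.93 ± 0.26) fell. Each gene named here moved the same way in 3 of 3 litters.

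Of 79 nuclear genes of oxidative phosphorylation, 44 fell and 0 rose in the HLHS left ventricle (67 fell adjusted over the list alone), with a median log2 change of −0.23 and, for example, Cox7a1 at −0.70 ± 0.08. Among 22 citric acid cycle genes, 20 fell (21 adjusted over the list alone, median −0.28), including Sdha (−0.38 ± 0.06), a subunit of succinate dehydrogenase. Of 32 fatty acid oxidation genes, 17 fell (23 adjusted over the list alone, median −0.34), with Acadvl at −0.65 ± 0.07 and Ppara, a transcription factor of lipid catabolism, at −0.93 ± 0.11. Camera's adjusted p was 2.33e-19, 8.67e-11 and 7.36e-17 for these 3 lists with a preset correlation, and 0.492, 0.466 and 0.327 with an estimated one, where none passed. The 12 mitochondrially encoded genes had a median of 0.00 and none passed (adjusted p = 0.925). Of 23 ion channel and conduction genes, 7 fell and 1 rose, both over all genes and adjusted over the list alone (adjusted p = 2.65e-04, and 0.327 with an estimated correlation). Kcnip2 (−1.62 ± 0.20) and Kcnd2 (−1.28 ± 0.11), which encode parts of the transient outward potassium current, were among those that fell.

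Of 26 hypoxia targets, 7 rose and 0 fell (10 rose adjusted over the list alone, median 0.25, camera adjusted p = 5.93e-07, and 0.492 with an estimated correlation), including the mitophagy receptor gene Bnip3 (0.93 ± 0.07) and the collagen cross-linking enzyme gene Loxl2 (0.80 ± 0.11). TGF-beta and BMP signalling had 7 of 29 members higher and 1 lower (11 and 1 adjusted over the list alone, adjusted p = 3.61e-05, 0.206 estimated), with the ligand genes Tgfb2 at 0.88 ± 0.06 and Bmp2 at 1.48 ± 0.20. The list of Wnt and Hippo targets had 8 of 17 higher and 0 lower (8 and 1 adjusted over the list alone, adjusted p = 1.3e-04, 0.206 estimated), with Rspo3 at 2.13 ± 0.24 and Sfrp1 at 0.52 ± 0.06. Both encode secreted Wnt regulators, and whether the output of these pathways changed was not tested. Of 15 cardiac stress genes, 5 rose by either adjustment (all genes or adjusted over the list alone, adjusted p = 1.84e-04, 0.492 estimated), among them Xirp2 (1.64 ± 0.21), the calcineurin regulator gene Rcan1 (0.53 ± 0.07) and Nppa, which encodes atrial natriuretic peptide (0.57 ± 0.09). The unfolded protein response list had 4 of 16 members higher (7 adjusted over the list alone, adjusted p = 6.14e-04, 0.515 estimated), including Pdia4 at 0.37 ± 0.09. The mean log2 CPM of this list, HLHS minus littermate controls, was 0.34 at E13.5, 0.42 at E14.5 and −0.066 at E17.5. For hypoxia targets it was 0.28, 0.46 and 0.051, and for cardiac stress genes 0.38, 0.60 and 0.11. These differences were thus smallest or reversed at E17.5. The immediate early and heat shock list had 5 of 19 higher by either adjustment (5 adjusted over the list alone, adjusted p = 0.00208, 0.492 estimated), including Hspa1a at 1.34 ± 0.29. Its mean log2 CPM, HLHS minus littermate controls, was 0.26 at E13.5 and 0.33 at both E14.5 and E17.5. The control left ventricles differed by 0.21 at E14.5 and 0.22 at E17.5. This list of stress-response genes was fixed as a check of sample quality, which was not tested apart from HLHS. Cell cycle genes had 10 of 58 higher and 1 lower (14 and 1 adjusted over the list alone, median 0.10, adjusted p = 0.00513, 0.492 estimated), with Espl1 at 0.31 ± 0.06. The Sin3-HDAC complex, to which SAP130 belongs, had 5 of 18 members higher and 1 lower (6 and 1 adjusted over the list alone, adjusted p = 0.0112, 0.492 estimated); Sinhcaf was at 0.41 ± 0.06. The 84 cytosolic ribosomal protein genes had 1 higher and 1 lower (0 and 0 adjusted over the list alone, median 0.08, adjusted p = 0.0173, 0.839 estimated).

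Markers of blood and vessels moved with these groups. Of 18 erythroid genes, 10 rose and 2 fell (12 and 2 adjusted over the list alone, median 0.71, camera adjusted p = 5.93e-07, and 0.492 with an estimated correlation), and the embryonic globin genes Hbb-y and Hba-x were at 1.30 ± 0.17 and 1.29 ± 0.24. Of 26 endothelial and endocardial genes, 7 fell and 2 rose (15 and 3 adjusted over the list alone, median −0.19, adjusted p = 0.00104, 0.492 estimated), with the tight junction gene Cldn5 at −1.08 ± 0.09 and Vwf, which encodes von Willebrand factor, at 0.57 ± 0.09. The 33 sarcomere genes had 5 higher and 4 lower (5 and 5 adjusted over the list alone, median −0.02, adjusted p = 0.888). Extracellular matrix and fibroblast genes had 6 of 31 higher and 7 lower (7 and 11 adjusted over the list alone, median −0.06, adjusted p = 0.888). The calcium pump gene Atp2a2 fell by 0.37 ± 0.07 and the smooth muscle gene Cnn1 rose by 1.60 ± 0.13. The 15 human HLHS candidate genes had 3 lower (3 adjusted over the list alone, adjusted p = 0.158).

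Sap130 (ENSMUSG00000024260), a subunit gene of the Sin3-HDAC complex for which the study is known, had a log2 change of −0.35 ± 0.08 in the left ventricle (33.2 against 40.4 CPM; adjusted p = 0.023 in edgeR's quasi-likelihood test) and of −0.42 ± 0.10 in the right (32.2 against 41.7; adjusted p = 0.0416), lower in 3 of 3 litters on both sides. It missed the threshold in 4 of the 8 fits of the left ventricle that leave out 1 embryo and in 6 of 8 of the right. In the left ventricle, Hand1 (−0.25 ± 0.09), a transcription factor gene of the left ventricle, Hand2 (−0.13 ± 0.06), Nppb (0.35 ± 0.17), Cdkn1a (0.08 ± 0.12) and the proliferation marker Mki67 (0.11 ± 0.08) did not pass. Pcdha9, the other gene for which the study is known, was not analysed here, since the count table holds no entry that matches its symbol.

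The calls of the left ventricle rest on comparing littermates: without stage as a replicate block, 1 gene passed. Leaving out HLHS replicate 2, control replicate 2 or control replicate 3 gave 845, 1138 or 1309 genes. None of the 15 lists that passed in camera with a preset correlation passed with an estimated correlation, where the smallest adjusted p was 0.206.

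**Figure D2:**
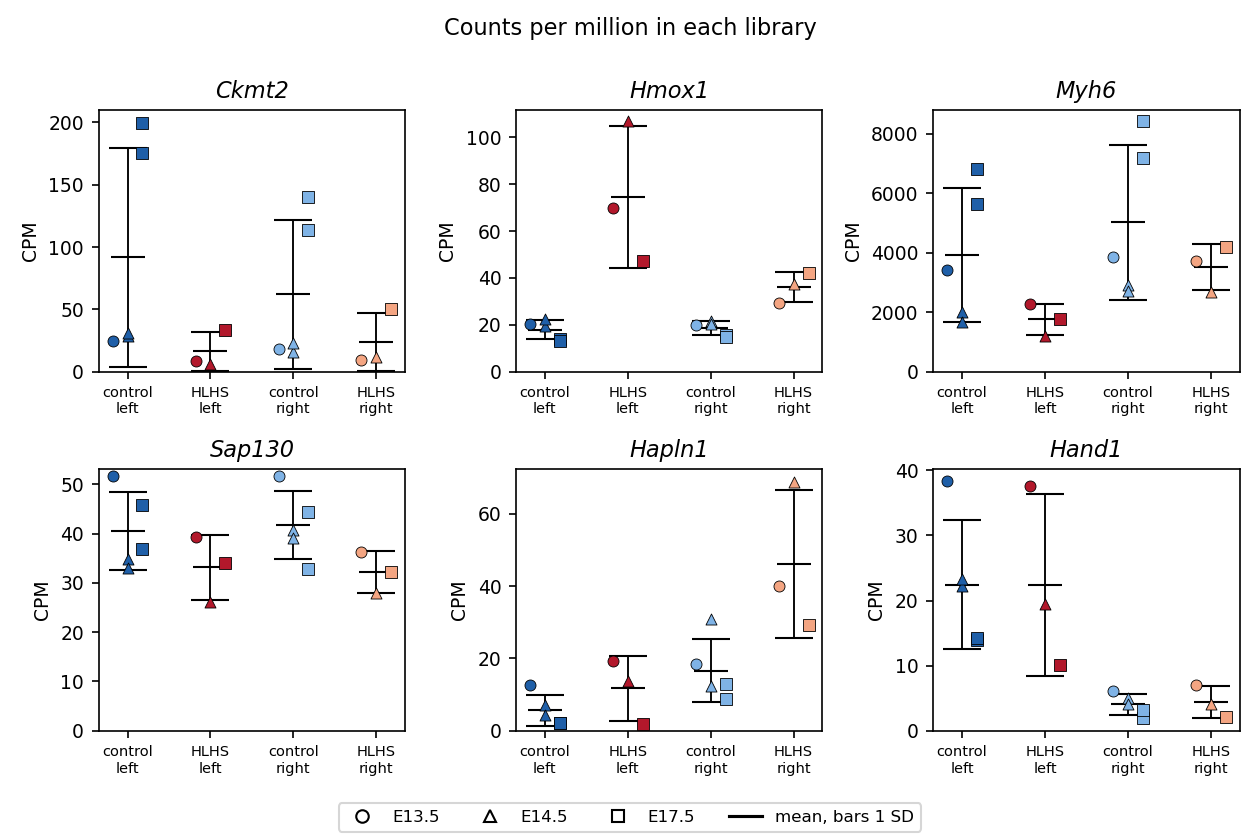
CPM of 6 genes in each library, by phenotype and side, with symbols for stage; horizontal lines are group means and bars 1 SD (5 control and 3 HLHS libraries per side). Hmox1 in the HLHS left ventricle lies above all control libraries, as does Hapln1 in 2 of the 3 HLHS right ventricles.

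In the HLHS right ventricle, some genes of extracellular matrix (9 of 31) and valve mesenchyme (4 of 15) were higher, and some sarcomere (9 of 33) and fatty acid oxidation genes (10 of 33) lower, than in littermate controls. As lists they passed in camera with a preset correlation and not with an estimated one (smallest adjusted p = 0.498). The cartilage-type collagen genes Col9a1, Col2a1 and Col9a3, which are also active in developing valves, rose by 1.80 ± 0.32, 1.63 ± 0.24 and 1.61 ± 0.33 on the log2 scale (SE, 3 HLHS and 5 control libraries). Acta1, the skeletal actin gene, changed by −0.76 ± 0.10. In edgeR's quasi-likelihood test with stage as a term, 1067 of 16142 genes passed after Benjamini-Hochberg adjustment, 575 higher and 492 lower. Of these, 80 were at least 2-fold higher and 79 at least 2-fold lower, and 1060 moved the same way in all 3 litters.

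The 10 largest changes in the right ventricle also included the ligand gene Wnt9b (1.56 ± 0.33), the Wnt inhibitor gene Sost (1.51 ± 0.17), the mast cell protease gene Cpa3 (−1.87 ± 0.31), Slc15a2 (−2.70 ± 0.61), Cavin4 (−1.63 ± 0.22), which encodes a caveolar protein of muscle, Dhrs7c (−1.54 ± 0.10) and the potassium channel gene Kcnn1 (−1.51 ± 0.17). Slc15a2 and Dhrs7c were thus among the 10 largest on both sides.

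Of 31 extracellular matrix and fibroblast genes, 9 rose and 0 fell in the HLHS right ventricle (22 and 1 adjusted over the list alone, median 0.49, camera adjusted p = 1.32e-12, and 0.516 with an estimated correlation), including Thbs1, which encodes thrombospondin 1, at 1.34 ± 0.23. Among 15 valve mesenchyme genes, 4 rose (11 adjusted over the list alone, median 0.64, adjusted p = 3.08e-09, 0.516 estimated), including the hyaluronan matrix genes Hapln1 (1.44 ± 0.24), Has2 (1.04 ± 0.22) and Vcan (0.76 ± 0.13). TGF-beta and BMP signalling had 8 of 29 higher (13 and 1 lower adjusted over the list alone, adjusted p = 4.88e-07, 0.516 estimated), with Bmp4 at 1.10 ± 0.17 and Tgfb2 at 0.67 ± 0.09. Of 19 genes in the list of Wnt and Hippo targets, 2 rose (11 adjusted over the list alone, adjusted p = 3.07e-06, 0.486 estimated): Wif1 at 0.84 ± 0.12 and Sfrp1 at 0.29 ± 0.07. Both encode secreted Wnt inhibitors, and pathway output was not tested here either. Epicardial markers had 4 of 15 higher (5 adjusted over the list alone, adjusted p = 1.52e-04, 0.564 estimated), with Krt18 at 0.66 ± 0.12. Macrophage and leukocyte markers had 2 of 16 higher (4 adjusted over the list alone, adjusted p = 1.52e-04, 0.582 estimated): F13a1 at 1.09 ± 0.10 and Mrc1 at 0.49 ± 0.10. Unfolded protein response genes had 4 of 16 higher (8 adjusted over the list alone, adjusted p = 1.59e-04, 0.582 estimated), with Pdia4 at 0.39 ± 0.07. Endothelial and endocardial markers, measured in the same libraries, had 2 of 26 lower (5 adjusted over the list alone, median −0.08, adjusted p = 0.0504), and erythroid markers 1 of 20 lower (1 adjusted over the list alone, median −0.05, adjusted p = 0.46).

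Of 33 sarcomere genes, 9 fell and 0 rose in the right ventricle (21 fell adjusted over the list alone, median −0.27, camera adjusted p = 2.77e-13, and 0.498 with an estimated correlation). Calcium handling genes had 4 of 21 lower (10 lower and 1 higher adjusted over the list alone, adjusted p = 1.52e-04, 0.498 estimated), with Trdn at −0.42 ± 0.06 and the calcium release channel gene Ryr2 at −0.40 ± 0.09. Of 24 ion channel genes, 7 fell and 1 rose (7 and 2 adjusted over the list alone, adjusted p = 4.96e-04, 0.498 estimated), with Kcnip2 at −0.93 ± 0.14. Of 33 fatty acid oxidation genes, 10 fell (19 adjusted over the list alone, median −0.30, adjusted p = 7.54e-12, 0.498 estimated), including Acsl1 (−0.71 ± 0.09) and Cd36 (−0.40 ± 0.07). Oxidative phosphorylation had 4 of 79 lower (4 adjusted over the list alone, median −0.20, adjusted p = 6.03e-12, 0.676 estimated), with Cox6a2 at −0.53 ± 0.10. The citric acid cycle had 0 of 22 lower (0 adjusted over the list alone, median −0.20, adjusted p = 2.33e-05, 0.668 estimated). At E14.5 the mean log2 CPM of these lists, HLHS minus controls, was −0.076 and −0.13, less than the difference between the control right ventricles (0.31 and 0.24). At E17.5 it was −0.36 and −0.31, against control differences of 0.27 and 0.17. The 26 hypoxia targets had 2 higher and 1 lower (3 and 4 adjusted over the list alone, median −0.02, adjusted p = 0.936).

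Cdkn1a, a cell cycle inhibitor gene, changed by −0.39 ± 0.07 in the right ventricle. Hand1 (−0.08 ± 0.18), Hand2 (−0.09 ± 0.08), Nppa (0.48 ± 0.16), Nppb (0.11 ± 0.25), Myh6 (−0.35 ± 0.16), Myh7 (−0.22 ± 0.09) and Mki67 (0.05 ± 0.10) did not pass. Without stage as a replicate block 0 genes passed in edgeR's quasi-likelihood test. Leaving out control replicates 1, 3 or 5 gave 195, 421 or 412 genes, leaving out HLHS replicates 1, 2 or 3 gave 198, 274 or 283, and a term for sex, added after seeing the data, gave 601. None of the 13 lists passed with an estimated correlation, where the smallest adjusted p was 0.486.

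**Figure D3:**
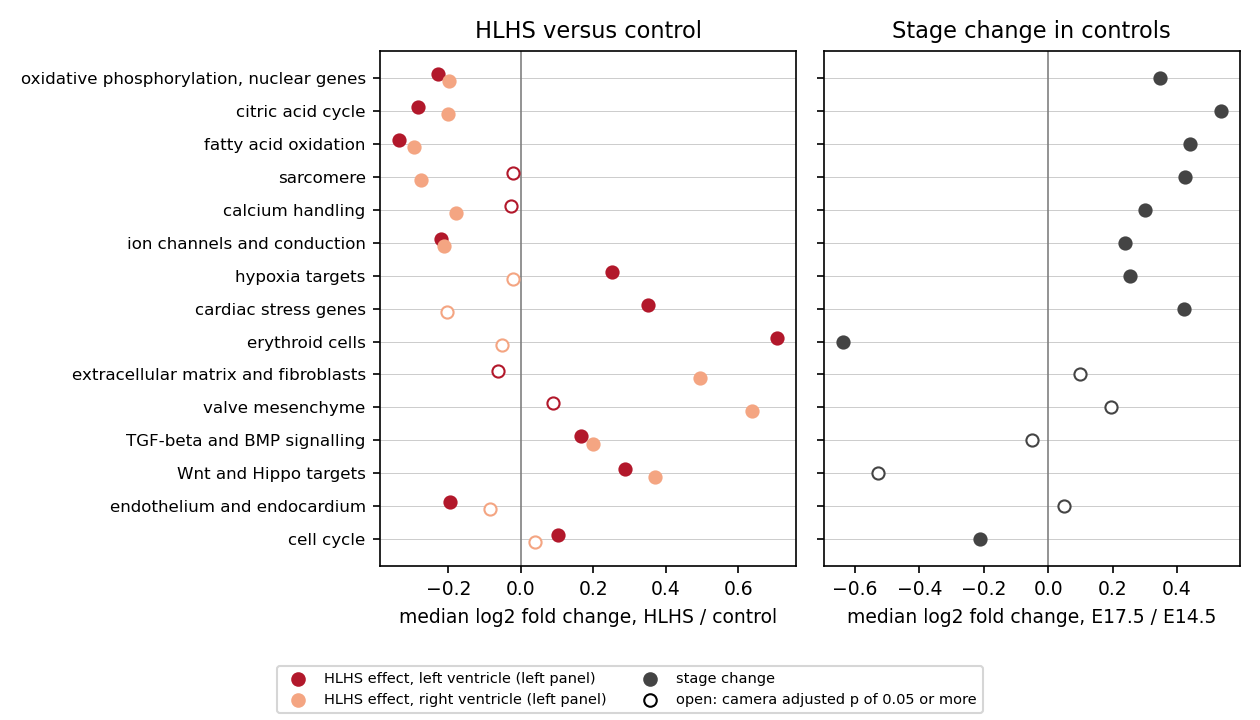
Median log2 fold change of 15 gene lists, HLHS over control in each ventricle (left panel) and E17.5 over E14.5 in controls (right panel); filled circles passed camera with a preset correlation of 0.01 and open circles did not. The median of oxidative phosphorylation was lower in HLHS (−0.23 left, −0.20 right) and higher at the later stage (0.35), while that of matrix genes was higher in the right ventricle (0.49). In the right ventricle 4 of 79 and 9 of 31 members of these lists passed, and with an estimated correlation neither list passed in any of these comparisons.

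Of 15750 genes tested on both sides, 253 were called higher in HLHS in both ventricles and 303 lower in both, while 4 and 3 were called in opposite directions. Of 2032 genes called in the left ventricle, 93.2% had the same sign in the right. Log2 changes correlated across genes with a Pearson r of 0.549 and a Spearman rho of 0.550. The ventricles come from the same embryos, and other groupings of them reached agreement of this size: of the 18 ways to pick 1 embryo per litter as HLHS, 3 gave an r as high, the real one included, and the other 17 ran from 0.215 to 0.591.

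Whether the HLHS effect differs between the ventricles was tested within embryos, as left minus right. The 3 genes that passed, all lower on the left relative to the right, were Tmem26, which encodes a membrane protein (−2.22 ± 0.28; SE, 8 embryos), Tppp, which encodes a tubulin polymerisation factor (−0.98 ± 0.11), and P4ha3, a collagen prolyl hydroxylase gene (−0.85 ± 0.11). They were among 16508 genes tested, with adjusted p of 0.0355, 0.0235 and 0.0377 in edgeR's quasi-likelihood test with the embryo as a block; 1411 genes had an unadjusted p under 0.05. The next smallest p belonged to Ckmt2 (−1.12 ± 0.16) and Mylk4 (−2.01 ± 0.30), both with an adjusted p of 0.0588. The count was 132 in DESeq2 (60.6% higher on the left), 5 in limma-voom (0%), 171 with a stage term for the side difference (51.5%), 217 with no count filter (49.3%) and 24 without the embryo as a replicate block (54.2%). The main fit held no stage term for the side difference, so it set HLHS embryos against controls of all litters. The fit with that term compared them within litters, as the tests of each ventricle do. In the main fit the count was 0 without control replicate 3, 4 or 5. It was 135 without HLHS replicate 3 (79.3%), 38 without control replicate 2 (42.1%) and 25 without HLHS replicate 1 (16.0%). The direction of the 3 genes thus does not extend to the larger counts.

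In 17 of 40 lists camera with a preset correlation called a difference between the sides, and in none with an estimated correlation (smallest adjusted p = 0.168). Matrix and fibroblast genes had a median difference of −0.41 with 0 of 31 members past the threshold (13 lower adjusted over the list alone, adjusted p = 5.74e-15), including Lum at −0.95 ± 0.22. Valve mesenchyme had a median of −0.61 (7 lower adjusted over the list alone), with Sox9 at −1.08 ± 0.21 and Prrx1 at −0.63 ± 0.12. Sarcomere genes had a median of 0.23 (10 and 1 lower adjusted over the list alone), erythroid genes of 0.68 (13 and 1 lower), with Hba-x at 1.24 ± 0.24, hypoxia targets of 0.27 (1), with Bnip3 at 0.65 ± 0.15, and cardiac stress genes of 0.27 (4), with Xirp2 at 2.02 ± 0.38. Over the 56 splits of the 8 embryos into 3 and 5, the left minus right list score differed between HLHS and control embryos with an exact two-sided permutation p of 0.0179 for sarcomere genes and hypoxia targets, 0.0357 for erythroid, 0.0536 for valve, 0.0714 for matrix and 0.0893 for cardiac stress genes. Adjusted over the 40 lists scored, this p was 0.397 for cardiac stress genes and 0.357, the smallest of any list, for each of the other 5. Of the 18 ways to pick 1 embryo per litter, only the real one gave as large a difference within litters for sarcomere genes, hypoxia targets and cardiac stress genes. For erythroid, valve and matrix genes 2 did, the real one included. With 18 choices a share under 0.05 cannot be reached. Values for Sap130 (0.08 ± 0.11), Hand1 (−0.14 ± 0.17), Hand2 (−0.03 ± 0.09), Nppa (0.09 ± 0.23), Nppb (0.27 ± 0.32), Myh6 (−0.61 ± 0.15), Myh7 (0.24 ± 0.12), Cdkn1a (0.46 ± 0.12), Mki67 (0.06 ± 0.10) and the muscle intermediate filament gene Des (0.51 ± 0.11) did not pass.

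**Figure D4:**
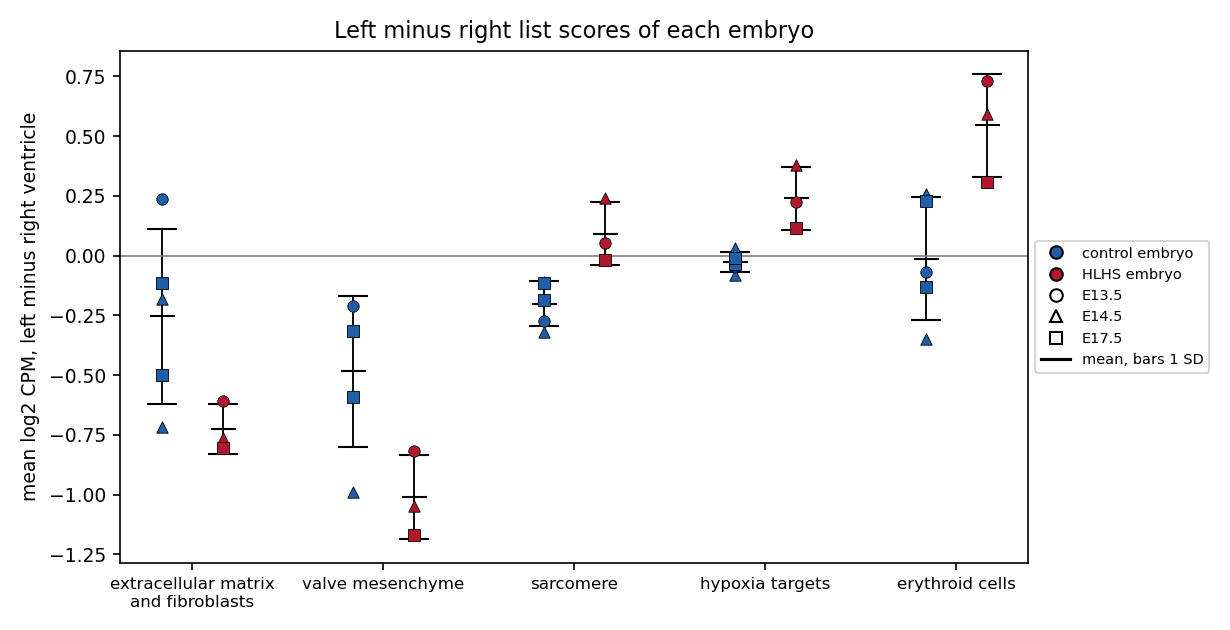
Mean log2 CPM of 5 gene lists in the left minus the right ventricle of each embryo, for 5 control and 3 HLHS embryos; lines are means and bars 1 SD. Sarcomere scores average 0.09 in HLHS and −0.20 in control embryos, and hypoxia scores 0.24 and −0.03.

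In control hearts, the left ventricle held more Hand1 (2.44 ± 0.10; SE, 5 embryos), Spp1, which encodes osteopontin (3.89 ± 0.36), Gtsf1 (2.79 ± 0.15) and Nrn1 (2.17 ± 0.12) than the right. The right ventricle held more of the outflow tract genes Isl1 (−5.68 ± 0.66) and Sema3c (−1.08 ± 0.13), of Sln, which encodes sarcolipin (−3.72 ± 0.33), of Mybpc1, a slow skeletal myosin-binding protein gene (−3.60 ± 0.26), and of Col9a1 (−2.93 ± 0.42), Ltbp2 (−2.70 ± 0.32), Rspo3 (−2.52 ± 0.28) and Abi3bp (−2.27 ± 0.24). With the embryo as a block, edgeR's quasi-likelihood test called 990 of 16238 genes, 339 higher on the left and 651 higher on the right, of which 948 had the same direction in all 5 embryos. The count was 619, 486 or 584 without control replicate 2, 3 or 5.

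Of 5 left-ventricle patterning genes, 4 were higher on the left in controls (4 and 1 lower adjusted over the list alone, camera adjusted p = 8.01e-24), with Gja5, a connexin gene of the conduction system, at 1.31 ± 0.10. This was the 1 list that also passed with an estimated correlation (adjusted p = 0.0176). Cell cycle genes were higher on the left in 21 of 58 cases and lower in 0 (48 adjusted over the list alone, median 0.19, adjusted p = 7.15e-21, and 0.357 with an estimated correlation), such as Ect2 (0.33 ± 0.05) and Kif11 (0.28 ± 0.04). Trabecular genes had 5 of 10 higher and 1 lower (6 and 2 adjusted over the list alone, adjusted p = 1.96e-08, 0.0676 estimated), including Cited1 (0.61 ± 0.06), Irx3 (0.35 ± 0.06) and Nppa (0.74 ± 0.13). Wnt and Hippo targets were lower on the left in 9 of 19 cases (11 adjusted over the list alone, adjusted p = 1.86e-13, 0.357 estimated), including Wif1 (−1.85 ± 0.10), and valve mesenchyme in 9 of 15 (11 adjusted over the list alone, adjusted p = 8.55e-10, 0.357 estimated), including Hapln1 (−1.69 ± 0.23) and Prrx1 (−0.66 ± 0.07). Sarcomere genes had 7 of 33 lower (12 adjusted over the list alone, adjusted p = 1.35e-07, 0.507 estimated), such as Myom2 (−1.32 ± 0.18) and Acta1 (−1.15 ± 0.12), and calcium handling 6 of 21 (7 adjusted over the list alone, adjusted p = 2.23e-07, 0.357 estimated), with Casq1 among them. Matrix and fibroblast genes were lower on the left in 5 of 31 cases (12 adjusted over the list alone, median −0.23, adjusted p = 7.27e-04, 0.779 estimated). Of 9 skeletal muscle markers, 2 were lower on the left (3 adjusted over the list alone, adjusted p = 5.36e-05, 0.142 estimated): Myh8 (−2.27 ± 0.21) and Pvalb (−3.12 ± 0.43). Of 13 atrial markers 4 were higher and 6 lower (4 and 6 adjusted over the list alone, adjusted p = 0.301), with Dkk3 at −1.42 ± 0.17. Other lists that passed with the preset correlation alone had medians of −0.81 (right-ventricle and outflow patterning), −0.19 (TGF-beta and BMP signalling), −0.18 (basement membrane) and −0.13 (neuregulin, FGF and VEGF signalling). Those of fatty acid oxidation (−0.091), cardiac stress (−0.090), neural (−0.17), epicardial (0.28), unfolded protein response (0.087) and ribosomal protein genes (0.091) passed too. Hand2 (−0.34 ± 0.04), Myh6 (−0.42 ± 0.08) and Cdkn1a (−0.32 ± 0.05) were lower on the left, while Sap130 (−0.05 ± 0.07), Nppb (0.37 ± 0.14), Myh7 (−0.16 ± 0.07) and Mki67 (0.15 ± 0.05) did not pass.

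In HLHS hearts the small left ventricle still held more Hand1 (2.32 ± 0.13; SE, 3 embryos), Spp1 (3.00 ± 0.28), Nrn1 (2.77 ± 0.23) and Cited1 (0.52 ± 0.10) than the right, and less Isl1 (−4.80 ± 0.60), Sema3c (−1.09 ± 0.21) and Mybpc1 (−3.51 ± 0.55). Other genes lower on the left were Col9a1 (−4.13 ± 0.54), Col9a3 (−3.35 ± 0.34), Matn4 (−2.96 ± 0.34), Abi3bp (−2.94 ± 0.24), Fbln5 (−2.93 ± 0.11), Col2a1 (−2.64 ± 0.32) and the Wnt effector gene Lef1 (−2.63 ± 0.50). In edgeR's quasi-likelihood test with the embryo as a block, 637 of 15771 genes passed, 181 higher on the left and 456 higher on the right, and 636 had the same direction in all 3 embryos. The count was 270 without HLHS replicate 2 and 1117 without HLHS replicate 3.

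Matrix and fibroblast genes, lower on the left in controls too, were so in HLHS hearts in 18 of 31 cases (24 adjusted over the list alone, median −0.55, camera adjusted p = 6.05e-41, and 0.37 with an estimated correlation), with Lum at −1.44 ± 0.10. Valve mesenchyme genes were lower in 10 of 15 (13 adjusted over the list alone, mean −1.04, adjusted p = 1.28e-26, 0.329 estimated), with Sox9 at −1.52 ± 0.11 and Prrx1 at −1.27 ± 0.10. Wnt and Hippo targets had 7 of 18 lower (9 adjusted over the list alone, adjusted p = 9.71e-11, 0.439 estimated), with Sfrp2 at −2.34 ± 0.15. Erythroid genes were higher on the left in 7 of 19 cases (14 and 1 lower adjusted over the list alone, adjusted p = 1.89e-14, 0.439 estimated), with Hba-x at 1.43 ± 0.15 and Hbb-y at 1.13 ± 0.14. Of 26 hypoxia targets 1 was higher (9 adjusted over the list alone, adjusted p = 3.79e-07, 0.439 estimated), Bnip3 at 0.68 ± 0.11. Other lists that passed with the preset correlation alone had medians of 0.70 (left-ventricle patterning), −0.78 (right-ventricle and outflow patterning), 0.28 (cell cycle), 0.16 (sarcomere), 0.21 (cardiac stress) and 0.15 (ribosomal proteins). Those of fatty acid oxidation (−0.18), TGF-beta and BMP signalling (−0.11), neuregulin, FGF and VEGF signalling (−0.068), basement membrane (−0.069), immediate early and heat shock (0.17) and integrated stress response genes (0.19) passed too. Nppa (0.85 ± 0.14) was higher and Myh6 (−1.01 ± 0.14) lower on the left, and Sap130 (0.05 ± 0.09), Hand2 (−0.36 ± 0.09), Nppb (0.66 ± 0.24), Myh7 (0.11 ± 0.14), Cdkn1a (0.16 ± 0.11) and Mki67 (0.23 ± 0.11) did not pass. Of 15623 genes tested in both kinds of heart, 64 were called higher on the left in both (3.88 for independent lists), 227 lower in both (18.2), and 0 in opposite directions.

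Between E14.5 and E17.5, many genes of oxidative metabolism and the sarcomere rose in control hearts, and embryonic globin genes and 24 of 58 cell cycle genes fell, though no list passed with an estimated correlation. Hbb-y and Hba-x fell by 5.64 ± 0.30 and 3.84 ± 0.31 on the log2 scale (SE, 2 embryos per stage, both ventricles summed). The complement gene C3 (4.02 ± 0.25), Ly6c1 (2.90 ± 0.18), Col5a3 (2.75 ± 0.15), Ckmt2 (2.68 ± 0.13) and Clec3b (2.66 ± 0.21) rose, and Col2a1 (−3.98 ± 0.36), Spp1 (−3.10 ± 0.92) and Rimklb (−2.64 ± 0.29) fell. Myh6 was at 1.62 ± 0.12. In edgeR's quasi-likelihood test 5013 of 17790 genes passed, 2693 higher and 2320 lower at E17.5. Each stage is 1 litter, so stage and litter cannot be told apart. The sample titles also give the E14.5 litter another prefix than the E13.5 and E17.5 litters. The labels do not say what it means, and it cannot be told apart from stage either.

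By E17.5, 24 of 33 sarcomere genes had risen and 0 had fallen (29 adjusted over the list alone, camera adjusted p = 7.63e-14, and 0.574 with an estimated correlation), with Myom2 at 1.98 ± 0.12. Oxidative phosphorylation genes rose in 44 of 79 cases (52 adjusted over the list alone, adjusted p = 7.86e-12, 0.91 estimated), with Cox6a2 at 0.87 ± 0.11. The citric acid cycle rose in 20 of 22 (22 adjusted over the list alone, adjusted p = 8.97e-11, 0.663 estimated), with Sdha at 0.62 ± 0.09. Fatty acid oxidation rose in 21 of 33 with 3 lower (21 and 4 adjusted over the list alone, adjusted p = 6.92e-07, 0.663 estimated), with Acsl1 at 0.97 ± 0.08 and Ppara at 1.55 ± 0.13. Hypoxia targets had 14 of 26 higher and 4 lower (15 and 4 adjusted over the list alone, median 0.26, adjusted p = 2.44e-04, 0.574 estimated), with Egln3 at 1.55 ± 0.08. Cardiac stress genes had 7 of 15 higher and 1 lower (9 and 1 adjusted over the list alone, adjusted p = 0.00146, 0.663 estimated), with Xirp2 at 2.21 ± 0.11. The unfolded protein response had 10 of 16 higher (10 adjusted over the list alone, adjusted p = 6.35e-05, 0.574 estimated), with Xbp1 at 0.89 ± 0.07. Cell cycle genes had 24 of 58 lower and 2 higher (29 and 5 adjusted over the list alone, adjusted p = 0.00146, 0.663 estimated), such as Cdk4 (−0.42 ± 0.08) and Ccnb1 (−0.37 ± 0.06). Other lists that passed with the preset correlation had medians of 0.30 (calcium handling), 0.24 (ion channels), 0.24 (mitochondrially encoded genes), −0.31 (trabecular genes), 0.37 (smooth muscle), −0.64 (erythroid genes) and 0.39 (immediate early and heat shock). None of the 15 passed with an estimated correlation (smallest adjusted p = 0.574). Hand1 (−0.76 ± 0.10) and Nppa (−0.33 ± 0.09) were lower and Cdkn1a (0.65 ± 0.09) higher at E17.5, and Sap130 (0.13 ± 0.12), Hand2 (0.08 ± 0.07), Nppb (0.76 ± 0.26), Myh7 (0.25 ± 0.08) and Mki67 (−0.21 ± 0.10) did not pass. In the right ventricle alone the count of genes was 2878.

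Genes that rose with stage in controls tended to be lower in HLHS hearts, and genes that fell with stage to be higher. In the left ventricle, 603 of the 1057 genes lower in HLHS rose with stage and 359 of 985 higher genes fell with stage, while 70 and 56 genes moved the same way in both. In the right ventricle these numbers were 297 of 492 and 268 of 573, with 22 and 20 the same way. Across genes the log2 changes correlated with a Pearson r of −0.254 in the left and −0.294 in the right ventricle. The control libraries enter both sides of this comparison, so 100 simulations of unchanged HLHS embryos against the same controls were made, and their r ran from −0.0359 to 0.0481 (left) and −0.0442 to 0.0573 (right). The simulations draw each library on its own and hold no differences that ventricles of an embryo share, so this range is too narrow for real embryos. With the controls split between the comparisons in 4 ways, r was −0.305 to −0.177 and −0.351 to −0.190. The simulations and splits used 16209 genes, for which the real r was −0.250 (left) and −0.289 (right). Without HLHS replicate 3, the E17.5 embryo, r was −0.0912 in the left and −0.152 in the right ventricle. Of the 18 ways to pick 1 embryo per litter as HLHS, 2 gave an r as low as the real one on each side, the real one included, and the other 17 ran from −0.290 to 0.368 (left) and −0.350 to 0.346 (right). Each choice refitted the stage change with its own controls, which called from 0 to 5056 genes between stages. These r are thus not a like-for-like reference. The other choice as low kept the HLHS embryos of E14.5 and E17.5 and called 5056 genes between stages.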

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

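All tests of explanations below were chosen only after the results they measure had been seen.

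Among 30 groups of 5 control values tested, 3 held a value far from the others, where chance gives about 1 in 20. Control right ventricle replicate 1 had 17081273 counts against 24362225 to 27146143 in the other control right ventricles. The same library held 1.37% of its counts in Myh7, against 1.04 to 1.09%. Hand2 was at 104 CPM in control left ventricle replicate 1 against 81.4 to 87.8 in the others. All 3 values came from control replicate 1, the only control embryo of E13.5, so stage and litter set it apart from the others. The chance rate takes 5 values of like samples, and these groups mix stages, so it does not hold here.

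The HLHS effect differed between the ventricles, left minus right, for Tppp (log2 difference −0.98), Tmem26 (−2.22) and P4ha3 (−0.85) in edgeR's quasi-likelihood test, with adjusted p of 0.0235, 0.0355 and 0.0377. Camera with a preset correlation called 17 lists in the same test, with these medians. They were 0.23 for sarcomere, 0.075 for calcium handling, 0.053 for cell cycle, −0.059 for oxidative phosphorylation, −0.12 for the citric acid cycle and −0.12 for fatty acid oxidation. They were 0.12 for glycolysis, 0.27 for hypoxia targets, −0.0091 for trabecular myocardium, 0.27 for cardiac stress genes, −0.41 for extracellular matrix and −0.61 for valve mesenchyme. They were 0.011 for smooth muscle, −0.45 for macrophages, 0.68 for erythroid cells, 0.17 for immediate early and heat shock genes and 0.18 for the integrated stress response. With an estimated correlation, none of the 17 passed.

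Other splits of the 8 embryos into 3 and 5 were fitted in the same way. In the left ventricle 1 of 54 splits gave as many genes as the real one (2043, highest other 546), and in the right 1 of 54 (1067, highest other 1). Most of these splits ignore the litter, which the fit holds as a term, so this share alone does not exclude chance. The 18 splits that match the design, with 1 HLHS embryo in each litter, are too few for a share under 0.05 (highest other 1 in each ventricle, and 0 for the difference between the ventricles). For the difference between the ventricles, 2 of 56 splits gave at least the real count of 3, and the other gave 78, many times the real count, which points to a structure of the samples. That split sets both E13.5 embryos and the HLHS embryo of E14.5 against the rest, and the origin of its count was not tested. For the control sides 1 of 100 drawn splits of the 10 libraries gave as many (990, highest other 468). The draw ignored the embryo, which the fit holds as a block, so this share alone does not exclude chance. The 16 splits that match the design, with sides exchanged within embryos, are too few for a share under 0.05 (highest other 0). For the HLHS sides the 10 splits are too few for a share under 0.05 (637 in the real one, 0 as the highest other; 1 split as large, the real one).

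HLHS ventricles lay on the earlier side of their littermate controls. Against shared control libraries as the origin, r was at most −0.177 (left) and −0.190 (right) in the 4 splits of the controls where no library enters both sides. Against fewer cardiomyocytes in the left ventricle, sarcomere genes had a median log2 change of −0.022 against −0.24 for oxidative genes, with a score above the oxidative one in 3 of 3 litters (mean gap 0.28, SD 0.16). In the right ventricle, where the median of sarcomere genes was as low (−0.27 against −0.20), this explanation stays open. A younger embryo as a whole stays open too. The embryonic share of globin counts was above the littermate mean in 3 of 3 litters on both sides (mean log2 ratio 0.92 left and 0.41 right, exact one-sided permutation p of 0.0556, the smallest that 18 choices allow, and 0.111). The ratio was 0.57 and 0.25 without control replicate 4, whose left library held 7 embryonic globin counts. Without control replicate 3 the share was above in 2 of 3 litters on the right. It also differed between ventricles of the same embryo, as in HLHS replicate 2 (9.77% left, 5.96% right). Higher in the HLHS left ventricle were 4 lists that also rose from E14.5 to E17.5, by a preset correlation only. They were hypoxia targets (median 0.26), cardiac stress (0.42), unfolded protein response (0.39) and immediate early and heat shock genes (0.39). At E17.5 a younger embryo would have lower scores of these lists. In the 1 HLHS embryo there, hypoxia (0.051), cardiac stress (0.11) and immediate early scores (0.33) were above controls by more than the control range. The unfolded protein response score was below controls at E17.5 (−0.066), so there it does not stand against a younger embryo. All but the immediate early list differed most at E13.5 and E14.5. The stage change before E14.5 was not measured, with 1 control embryo at E13.5, so the lists cannot decide there. The choice of embryos within litters stays open, because 18 choices cannot give a share under 0.05. Of these, 2 gave an r as low in each ventricle, the real one included, and the others ran from −0.290 to 0.368 (left) and −0.350 to 0.346 (right). The other choice as low kept the HLHS embryos of E14.5 and E17.5. Each choice refitted the stage change with its own controls, so these r are not a like-for-like reference.

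Some matrix (9 of 31) and valve genes (4 of 15) were higher in the HLHS right ventricle, as lists by a preset correlation only. Against fewer cardiomyocytes as the whole origin, which would raise all other cell types alike, endothelial markers had a median log2 change of −0.084 against 0.49 for matrix genes, with a lower score in 3 of 3 litters (mean gap 0.63, SD 0.44). As a part it stays open. Medians were negative for sarcomere (−0.27, 9 of 33 members lower) and calcium handling lists (−0.18, 4 of 21). They were positive for epicardial (0.34, 4 of 15 higher) and macrophage lists (0.29, 2 of 16), all by a preset correlation only. Against a younger embryo as the whole origin, matrix and valve genes had medians of 0.10 and 0.20 from E14.5 to E17.5 (SD of the members 0.49 and 0.61), where it would need falls of about 0.49 and 0.64; 12 of 31 and 6 of 15 members did fall, so it stays open for those. Valve or outflow tissue taken along with the right ventricle stays open too: valve markers had a median change of 0.64 (4 of 15 past the threshold), which carried-over tissue could give as well as a change within the ventricle. At E14.5 the control right ventricles differed by 0.79 in valve and 0.48 in matrix score, more than HLHS from controls (0.62 and 0.30). At E17.5 the HLHS differences (0.56 and 0.42) exceeded the control ranges (0.13 and 0.17). A change of the fibroblasts or valve cells themselves was not tested apart from these.

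Control right ventricle replicate 4 came from an embryo with Y-linked transcripts (Ddx3y at 77.0 CPM) and yet held Xist at 34.7 CPM. Against an embryo that carries both kinds of transcript stands the left ventricle of the same animal, where Xist was at 1.25 CPM. RNA of a female heart mixed into the library may be the source, at 3.36% of the mean Xist level of female control right ventricles. The log2 right over left ratio of the Y-linked genes was −0.17 in this embryo, below the −0.12 to 0.16 of the other male embryos and so in the direction that mixing predicts. The predicted shift of −0.05 is smaller than that range, so this cannot be told apart from other sources, and no other biological explanation was tested.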

How the results depend on the processing

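The term for sex was chosen after seeing the data; the other settings were planned. The cause of a change was not tested unless named. Counts of genes: for HLHS versus control, left ventricle (2043), 1 without the replicate block; for HLHS versus control, right ventricle (1067), 1720 with no count filter, 0 without the replicate block, 1662 with all 16 libraries in one fit, 2401 with ventricles summed per embryo and 601 with sex as a further term. For the HLHS effect, left minus right ventricle (3), DESeq2 gave 132, limma-voom 5, no count filter 217, no replicate block 24 and a stage term for the side difference 171. With no count filter, left versus right ventricle gave 1570 in controls (990) and 1309 in HLHS (637). For E17.5 versus E14.5, controls (5013), the right ventricle only gave 2878. In every other planned setting not leaving out an embryo, these counts were within 1.5 times the count reported.

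Leaving out 1 embryo gave 845 to 2309 (HLHS versus control, left ventricle), 195 to 1518 (HLHS versus control, right ventricle), 0 to 135 (HLHS effect, left minus right ventricle), 486 to 883 (left versus right ventricle, controls), 270 to 1117 (left versus right ventricle, HLHS) and 3829 to 5043 (E17.5 versus E14.5, controls) genes. Fits without an HLHS or control embryo at E13.5 hold no HLHS contrast at that stage. Correlations with the stage change were refitted without each HLHS embryo only, and kept their sign.

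Lists that passed numbered 15, 13, 17, 19, 17 and 15 in the 6 comparisons in this order. With an estimated correlation they numbered 0, 0, 0, 1, 0 and 0, and with fry, which tests whether a list moves on balance and not against other genes, 6, 0, 0, 9, 0 and 3. Single lists changed direction, as medians. With ventricles summed per embryo, extracellular matrix and fibroblasts passed at 0.24 (left, −0.062 before), hypoxia targets at 0.11 (right, −0.021) and erythroid cells at 0.35 (right, −0.050). Leaving out 1 embryo, for left minus right, cell cycle ran from −0.049 to 0.11, oxidative phosphorylation, nuclear genes, from −0.16 to 0.074 and passed in both directions, and unfolded protein response, not called before, passed at −0.089. For left versus right, oxidative phosphorylation, nuclear genes, passed at −0.032 and 0.061 in controls, and at −0.11 and 0.10 in HLHS. Between stages, sex-linked genes passed at −0.83 without control replicate 2.

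Log2 fold changes of genes that had not passed, and of Nppa between stages, changed sign. In HLHS versus control, left ventricle, Hand1 was at 0.0037 without the block, and Myh7 at −0.10 and Cdkn1a at −0.17 with ventricles summed. Leaving out 1 embryo, Myh7 ran from −0.0048 to 0.060 and Cdkn1a from −0.13 to 0.26. In the right ventricle Hand1 was at 0.12 without the block; leaving out 1 embryo, Hand1 ran from −0.19 to 0.025, Hand2 from −0.23 to 0.024, Nppb from −0.058 to 0.36 and Mki67 from −0.075 to 0.20. For left minus right, Hand2 ran from −0.14 to 0.047, Nppa from −0.073 to 0.32, Nppb from −0.034 to 0.71 and Mki67 from −0.055 to 0.16. For left versus right, Sap130 in controls ran from −0.11 to 0.016 and Cdkn1a in HLHS from −0.0040 to 0.29. Between stages, the right ventricle only gave Sap130 at −0.037 and Nppa at 0.00035, and Sap130 ran from −0.063 to 0.30 without 1 embryo. No called gene named in the other comparisons changed sign. Of 31 genes named as called in the right ventricle, 73 of 248 fits without 1 embryo lost the call; in the left, 20 of 288. At the depth here, simulations recovered 77.6% of 1.5-fold changes in each ventricle, in genes drawn from those with higher counts. Recovery of smaller changes gene by gene was not measured.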

Other observations

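The tests reported here were chosen after the results had been seen. Embryonic globins made up 21.8% of globin counts in the HLHS left ventricle at E13.5 (95% Wilson interval 21.3 to 22.3%, counting error only), against 15.4% in the littermate control. The values were 9.77% at E14.5 (9.44 to 10.1%) against 8.50 and 4.93%, and 0.429% at E17.5 (0.343 to 0.535%) against 0.0655 and 0.282%. In the right ventricle HLHS and control libraries held 18.1 and 14.6% at E13.5, 5.96% against 5.98 and 3.90% at E14.5, and 0.310% against 0.147 and 0.284% at E17.5. Since reads of near-identical globin genes cannot be told apart, these shares take the assignment in the deposited counts as given.

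Xist and Ddx3y gave both ventricles of each embryo the same sex, with 4 male and 4 female embryos. At E13.5 the HLHS embryo was female and its control male, so in that litter sex and HLHS cannot be told apart. The HLHS embryo was female at E14.5 and male at E17.5, each with a male and a female control. Xist ran from 776 to 1132 CPM in female libraries.

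With sex as a further term, the correlation of the HLHS effect with the stage change was −0.283 in the left and −0.290 in the right ventricle.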
